A study of Mus musculus with 15 samples.

How the data were processed

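The series profiled chromatin in the nucleus accumbens, a forebrain region of reward and motivation, of C57BL/6 mice after chronic social defeat stress. Per the labels' protocols, mice were defeated by aggressive CD1 mice on 10 days, and a social interaction test then parted the defeated mice into susceptible (avoiding) and resilient (not avoiding) groups, beside undefeated controls. Tissue was taken 48 hours after the last defeat, and punches from 10 mice were pooled per replicate. Chromatin was sheared for ACF1 and SNF2H, the 2 subunits of the ACF remodelling complex, or digested with micrococcal nuclease for histone H3, and then immunoprecipitated. Libraries were amplified with 19 PCR cycles for ACF1 and SNF2H and 15 for H3, and were sequenced with 100 bp reads, per the labels. The labels tell of replicates per group, but each group had 1 sample per target and each deposited file held 1 result per group or per pair of groups. No spread between replicates could be taken from them, and no p-value given here compares groups of animals.

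Of the 15 samples, the 3 ACF1 samples and the 3 H3 samples had files; SNF2H and the input libraries were not analysed here. Per the submitters' processing notes, CASAVA 1.8.2 and the build mm9 were used; the aligner and the programs that made the segments and the H3 tables are not given in the sources used here. Each of the 3 deposited ACF1 files divided every chromosome into 2 states, E1 and E2, in steps of 200 bp, with no score or read count. Nothing in the files says which state stands for ACF1 binding, so the minority state E2 was analysed and is called a segment in what follows. The 6 deposited H3 tables held positions the authors had selected: for each pair of groups, 1 table of occupancy changes marked Up or Down and 1 table of nucleosome shifts in bp. They gave no p-value, size of the occupancy change, read count or list of positions tested and not selected. Which 2 groups a table compares, and their order, was read from the names under which the tables were deposited. Up was taken to mean higher in the first-named group; the files do not state this, and with the opposite reading every H3 direction given here turns round. Depth is unknown for all files, so no counting interval was computed.

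From these files, numbers were counted, and shares of Up positions were given 95% intervals from 2000 bootstrap resamples of 1 Mb blocks, which cover clustering along the genome and not differences between animals. Overlap of segments (at least 1 bp) was set against 10000 rotations of 1 list along each chromosome, one-sided. H3 positions within 1000 bp of a segment were set against 10000 rotations of the segments, two-sided, with Benjamini-Hochberg adjustment over the 18 pairs of lists. The direction of H3 positions near segments was tested by 10000 shuffles of the order of the 1 Mb blocks of signs, two-sided. The smallest p these permutation tests can give is 0.0001 one-sided and 0.0002 two-sided. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Coordinates are 1-based for segments and positions, and gene bounds are as the H3 tables give them, all on mm9.

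The tests were tried on simulated positions and signs laid over the susceptible segments and the resilient against control table. With no planted effect, 3 of 100 simulations passed 0.05 in the rotation test of 5000 positions, and 3 of 100 in the direction test of 16132 positions. The positions of the rotation test were spread evenly, and signs were drawn independently within blocks. These rates thus say nothing of positions piled up at a few loci with signs nearly all alike. All 100 simulations passed with 100 positions planted at segments and with a planted difference of 20 percentage points, which was recovered as 19.9. The gene test recovered 9.58 of 10 planted genes on average among 113 genes; the planted genes were the 10 with the most positions, set to 95% Up, so this says nothing of genes with few positions.

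Tests, alternatives and gene lists were fixed before the data were examined, with these exceptions, chosen after seeing the data: leaving out chromosome 1, positions within 100 bp counted as shared, splitting segments by the number of lists that hold them, the gene tests, the odds of lying on chromosome 1, the difference in direction between tables, and the tests of possible causes. Of the last, the one leaving out the fullest blocks was set down before its own result was seen. The planned gene-list test needs an annotation of the build of the files, which was not used here. In its place, the list genes that held a position were counted against 10000 draws of genes of like length from the 7815 genes named in any H3 table, and the direction of their positions against draws of genes with about as many positions, both outside chromosome 1. A gene with at least 5 positions was tested for its direction with an exact binomial test against the share of Up among positions in genes of its table, adjusted by the Benjamini-Hochberg method. Symbols and gene bounds came from the H3 tables; gene order, for 1 test of gene neighbours, came from RefSeq's GRCm38.p6 annotation, of which no coordinate is printed.

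The rule for named regions took the 5 widest segments of each list, of the susceptible list alone and of those in all 3 lists, and the 5 largest shifts of each table, overall and near susceptible segments. Its part on the largest occupancy gains and losses could not be applied, since the tables rank none, and list genes were taken in order of their number of positions instead. Other genes named below were chosen after their values were seen. Some results of genes and gene lists are not reported here.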

Results

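The data consisted of 3 genome-wide segmentations of ACF1 ChIP-seq, 1 each for control, susceptible and resilient mice, and of the authors' H3 tables for the 3 pairs of these groups. ACF1, encoded by Baz1a, is the accessory subunit of the ACF complex, which spaces and slides nucleosomes. Each group stood for 1 deposited result, so there was no spread between replicates for any value, and depth was unknown.

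ACF1 segments were more numerous in the susceptible list than in the others. The susceptible list held 1133 segments covering 4239 kb, the control list 749 covering 2610.6 kb, and the resilient list 716 covering 2859.4 kb. The susceptible list thus had 1.51 times as many segments as the control list, while the resilient list had 0.956 times as many. The minority state took up 0.160% of the listed genome in susceptible mice, 0.0983% in controls and 0.108% in resilient mice. Median widths were 1000 bp, 1000 bp and 1200 bp. No test of these differences was possible with 1 list per group.

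Several of the widest segments lay at the same regions in every list. On chromosome 8, positions 19917001 to 20037200 formed the widest susceptible segment, 120200 bp over Gm15319, 2610005L07Rik and 6820431F20Rik, where the widest control segment was 63800 bp and the widest resilient one 62000 bp. The other lists covered most of the same genes in split segments, with 34633 bp of 2610005L07Rik in controls, 34600 bp in resilient and 39033 bp in susceptible mice. On chromosome 1, a segment over Sp110 and Sp140, which encode nuclear body proteins of immune cells, spanned 76000 bp in controls, 71400 bp in susceptible and 62800 bp in resilient mice. A segment from 85229401 to 85330200 of the same chromosome, over C130026I21Rik, spanned 100800 bp in susceptible and 85600 bp in resilient mice. On chromosome 11, the segment over Sfi1, a centrosomal protein gene, spanned 54800 bp in controls and 88600 bp in susceptible mice, where it was joined to that over Pisd-ps1 and Pisd-ps3. In controls a separate segment covered Pisd-ps1 to the same length (7924 bp), and Sfi1 was covered over 56614 bp against 61614 bp, so most of the difference in width is a split. On chromosome X, the interval from 121263401 to 121325800, with no gene named in the tables, was 62400 bp wide in susceptible, 62200 bp in resilient and 63400 bp in control mice. The remaining wide segments were on chromosome Y in controls (56000 bp) and over Gm13251 on chromosome 4 in resilient mice (62400 bp). All of these were present in all 3 lists. Segments of at least 10 kb made up 57.3% of the covered length in controls, 58.8% in resilient and 57.6% in susceptible mice.

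**Figure D1:**
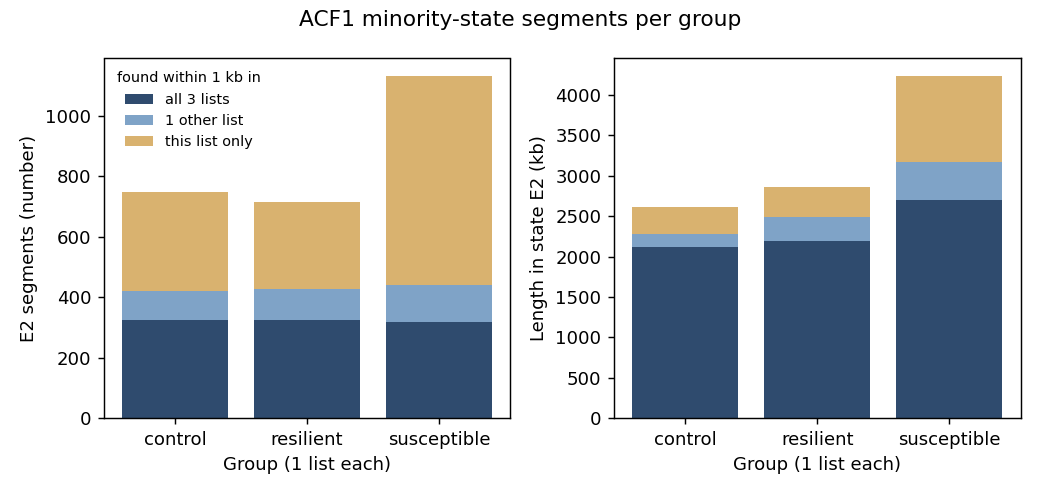
ACF1 segments of state E2 per group, as a number (left) and as covered length in kb (right), with 1 list per group and no error. Colours part segments by whether the other lists held a segment within 1 kb. Segments found in all 3 lists numbered 319 to 326 per group, and those of 1 list only numbered 691 in susceptible mice, 329 in controls and 288 in resilient mice.

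The lists shared far more segments than rotation gave. Of the control segments, 391 (52.2%) overlapped a susceptible segment, against 4.27 ± 2.98 (SD over 10000 rotations), and 355 overlapped a resilient segment, against 4.42. Of the resilient segments, 397 (55.4%) overlapped a susceptible one, against 5.05. Each of these permutation tests reached p = 0.0001, one-sided, the smallest they can give. Chromosomes X and Y held 33.5% of the covered length in controls, 33.7% in resilient and 24.1% in susceptible mice. Rotation does not hold the mapping of reads fixed, so reads shared between gene copies could also give this overlap, which was not tested. Segments in all 3 lists were wide, with medians of 1800 bp in controls, 1600 bp in resilient and 2600 bp in susceptible mice. They held 81.3%, 76.5% and 63.6% of the covered length.

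Segments of the susceptible list alone, with no control or resilient segment within 1000 bp, numbered 691 (61.0% of that list) and had a median width of 1000 bp. The widest, on chromosome 17 from 13407201 to 13435400, covered 28200 bp over Smok2a and Smok2b, members of a family of testis-expressed sperm motility kinases. The next was on chromosome 7 from 39198801 to 39225800 (27000 bp), followed by chromosome X from 4226801 to 4251200 (24400 bp) and chromosome 4 from 3152601 to 3167600 (15000 bp), none with a gene named in the tables. A segment of 18000 bp on chromosome 4 from 145666601 to 145684600 lay over 1700095A21Rik and Gm13247. Among the 7815 genes with bounds in the tables, 290 held a segment in some list: 199 in susceptible, 148 in control and 115 in resilient mice. Of these, 72 held some segment in each list, including Sfi1, Mid1, Gm13152 and Nlgn1. Of the 102 genes with a susceptible segment only, Cyp3a41a held 8200 bp in 3 segments, Hjurp, a centromere chaperone gene, 6170 bp, and Runx1, a haematopoietic transcription factor gene, 3000 bp. Hjurp overlaps Mroh2a, which was covered over 35270 bp by 1 susceptible segment and over 14406 bp by 2 control segments. A gene with a susceptible segment only may thus lie beside segments of other lists. The 59 genes with a control segment only and the 29 with a resilient segment only show that list-specific segments were present in every group.

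Susceptible against control mice set stressed animals that avoided others against undefeated animals. The authors' deposited table listed 49408 occupancy positions, of which 42105 were Down and 7303 Up (14.8% Up, 95% interval 13.5 to 16.3). Chromosome 1 held 32791 of them, 66.4% of the table on 7.43% of the listed genome, and 98.2% of those were Down. Long genes of that chromosome led the table: Thsd7b had 195 Down positions, Pard3b 195 and the neuregulin receptor gene Erbb4 122. In resilient against control, Thsd7b held 6 positions, Pard3b 8 and Erbb4 3, and the whole of chromosome 1 held 1406. Down positions changed from 5.51 per Mb before 19.7 Mb of chromosome 1 to 180.9 per Mb after it, while the other autosomes held 4.44 per Mb. Up positions were level at 3.65 and 2.96 per Mb on the 2 sides, and 2.99 on the other autosomes. Without chromosome 1, the table held 16617 positions and 40.4% were Up (39.6 to 41.2).

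**Figure D2:**
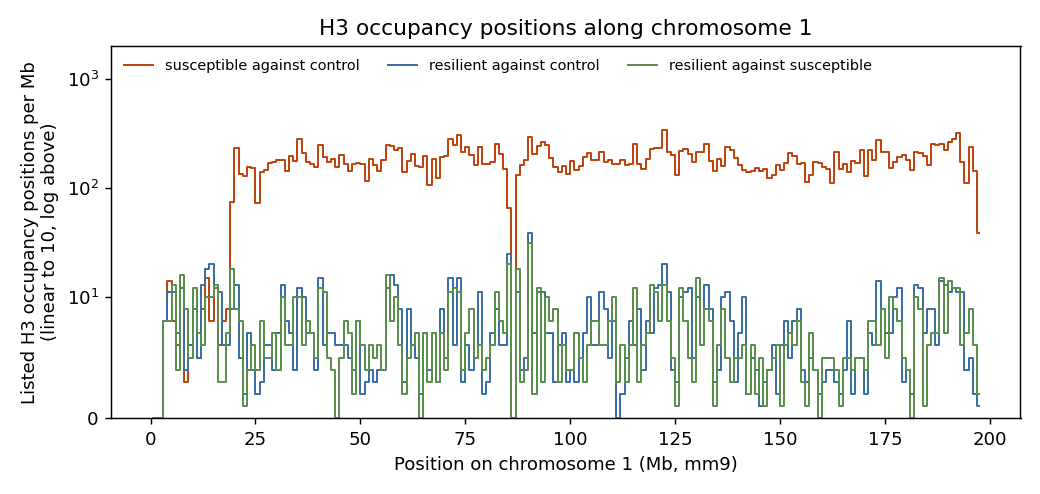
Number of H3 occupancy positions listed per Mb of chromosome 1 (y axis linear to 10 and logarithmic above, x axis in Mb of mm9) for the 3 comparisons, 1 table each. Susceptible against control steps up near 19.7 Mb and stays high, with 32791 positions on the chromosome against 1406 and 1310 in the other tables.

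Outside chromosome 1, the positions listed at Mid1 and Sfi1 were mostly Up in susceptible against control. Mid1, which encodes a microtubule-associated ubiquitin ligase on chromosome X, held 14 Up positions of 16, within 17.8 kb (exact binomial test, adjusted p = 0.00581). The base of that test was 37.6% Up, whereas chromosome X as a whole held 53 Up of 83 positions, those of Mid1 among them. Sfi1 held 24 Up of 35 (exact test, adjusted p = 0.016). These were the genes past the threshold among 103 with at least 5 positions, and 6 had an unadjusted p under 0.05. Those others included Asic2, a proton-gated channel gene, with 6 Up of 7, and the alpha-catenin gene Ctnna3, with 10 Down of 10 (exact test, adjusted p = 0.436 for both). Both called genes carried ACF1 segments in every list, and positions within 1 gene are not independent, so these p-values are smaller than they should be. Promoter classes held 752 positions in 708 genes.

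Few genes of the fixed lists stood out in susceptible against control. Of the glutamate receptor and synapse list, 9 of 15 genes named in the tables held a position, and 15 of their 25 positions were Up, 7 of 10 at the synaptic adhesion gene Nlgn1. The adhesion and axon guidance list had 7 of 14 genes with positions, against 10.9 in length-matched draws (permutation p = 0.0306, adjusted p = 0.81), with 21 of 31 positions Down, among them 7 of 9 at Cdh13 and 4 of 4 at Cntn4. Medium spiny neuron genes, the identity list of the main cell type of this region, held no position, against 2.43 in draws (permutation p = 0.036, adjusted p = 0.81). Only 4 of the 16 genes of that list entered the test, those named in any table, and all 4 were named in resilient against control. Growth factor genes had 7 Down of 13 positions, 5 of 8 at Nrg3, ion channel genes 8 Down of 11, GABA receptor genes 5 Down of 6, and ISWI and other remodeller genes 6 Down of 7. Immediate early and stress signalling genes held 1 position each. Markers of endothelium had 5 Down of 9, of cortical excitatory neurons 5 Down of 6, and of oligodendrocytes 1 Down of 3, while astrocyte and microglia markers held 1 position each. On chromosome 1, the positions of Kcnq5 (36), Hsd11b1, which regenerates active glucocorticoid (7), and Creb1 (5) were all Down. Since 98.2% of all positions on that chromosome were Down here, these genes do not stand out from it. Of the 5 list genes with at least 5 positions outside chromosome 1, 0 passed when adjusted over the list alone, and 1, Nlgn1, had an unadjusted p under 0.05.

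Resilient against control mice addressed what differed in stressed animals that did not avoid others. The authors' deposited table held 17538 occupancy positions, 10822 Down and 6716 Up (38.3% Up, 37.4 to 39.1), with no excess on chromosome 1. Fhit, a nucleotide hydrolase gene in a fragile site, held 16 Up of 21 positions (exact binomial test, adjusted p = 0.0375). Sfi1 held mostly Down positions here, 22 Down of 23 (exact test, adjusted p = 0.0398). Next came Gm13152 with 26 Down of 29 (exact test, adjusted p = 0.114), Mid1 with 8 Down of 8 and the ribosomal RNA precursor Rn45s with 9 Down of 9 (adjusted p = 0.588 for both). Of 113 genes, 2 passed the threshold and 6 had an unadjusted p under 0.05. Promoter classes held 690 positions outside chromosome 1.

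The fixed lists showed no shift of direction in resilient against control. All 4 medium spiny neuron genes named in the tables held 1 position each, Up at Drd2, the dopamine D2 receptor gene, at Foxp1 and at Rgs9, and Down at Tac1, against 2.54 in draws (permutation p = 0.295). The glutamate list had 14 Down of 21 positions, with 4 of 4 Down at the presynaptic adhesion gene Nrxn3, and the ion channel list 12 Down of 16, with 6 of 6 at Kcnj6, which encodes a G protein-gated potassium channel. The adhesion list had 21 Up of 40, including 5 of 12 at Cdh13, 4 of 7 at Cntnap2 and 3 of 5 at Dscam. Growth factor genes had 8 Down of 13, stress signalling genes 3 Down of 4, with 2 at Crhr2, remodeller genes 2 Down of 4, with 1 Up and 1 Down at Baz1a, GABA receptor genes 1 Down of 2, and the immediate early list 1 position. Oligodendrocyte markers had 5 Down of 5, microglia markers 3 Down of 3, endothelial markers 7 Down of 11, cortical excitatory markers 5 Down of 7 and astrocyte markers 1 Down of 3. Of 7 list genes with at least 5 positions, 0 passed when adjusted over the list alone, and 0 had an unadjusted p under 0.05.

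Resilient against susceptible mice compared the outcomes of the same stress. The authors' deposited table held 16273 positions, 8319 Down and 7954 Up (48.9% Up, 48.0 to 49.7). Mid1 was Down at 27 of 27 positions and Sfi1 at 26 of 26 (exact binomial test, adjusted p = 1.34e-06 for both), but the 27 positions of Mid1 lay within 19.3 kb, and the test counts neighbouring positions of 1 locus as independent. Chromosome X as a whole held 72 Down of 101 positions, those of Mid1 among them. Gm13152 was Down at 16 of 19 (exact test, adjusted p = 0.132). All positions were Up at Prkg1 (6), at the kainate receptor gene Grik4 (5) and at Sema5a (5), with adjusted p of the exact test of 0.338, 0.339 and 0.339. Of 89 genes, 2 passed and 8 had an unadjusted p under 0.05.

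In the same table, the glutamate list had 15 Up of 30 positions over 12 genes, with 7 of 11 Up at Nlgn1 and 4 of 5 Down at Grin2a, an NMDA receptor subunit gene. The adhesion list had 14 Up of 23, with 5 of 7 at Dscam. Ion channel genes had 5 Down of 8, GABA receptor genes 3 Down of 5, growth factor genes 4 Down of 7, remodeller genes 5 Down of 8 with 2 at Baz2a, and stress signalling genes 1 Down of 2. The immediate early list and the medium spiny neuron list held 1 position each, the latter Up at Drd2. Markers of cortical excitatory neurons had 3 Up of 5, of endothelium 2 Up of 5, of astrocytes and microglia 2 Up of 2 each, and of oligodendrocytes 1 Up. Over the 3 tables, 0 of 45 tests of number and 0 of 44 of direction passed after adjustment, and 2 and 0 had an unadjusted permutation p under 0.05. Of the 4 list genes with at least 5 positions, 0 passed when adjusted over the list alone, and 0 had an unadjusted p under 0.05.

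The 3 tables named many of the same positions. Outside chromosome 1, susceptible against control and resilient against control shared 2216 exact positions, against 0.645 after rotation, and 2204 of these were Down in both, that is, highest in controls. They included 7 positions at Sfi1, 5 at Rn45s and 4 at Skint5. Positions higher in susceptible than in both other groups numbered 1518, with 10 at Sfi1 and 3 at Mid1. Positions higher in resilient than in both others numbered 1410, with 4 at Schip1 and 3 at Grik4. Positions lower in 1 group than in both others were rare, at 7 for controls, 5 for susceptible and 4 for resilient mice. Their number depended on exact matching. Over all chromosomes it was 7, 11 and 4 at exact positions and 26, 109 and 62 within 100 bp. The numbers of positions higher in 1 group changed little, from 2611, 1653 and 1547 to 2617, 1658 and 1550. Each pair of tables shares a group, and that group's library alone can give shared positions with these directions. Rotation does not keep this, so 0.645 is not the number to expect from unchanged groups. A simulation of unchanged groups was not possible without values per library. On chromosome 1, 182 positions were Down in susceptible against control and Down in resilient against susceptible, against 0 outside it; these rest on the excess of Down positions there, so no order of the groups is drawn from them.

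Nucleosome shifts were fewer. The authors' deposited tables listed 3942 shifts in susceptible against control, 3363 of them on chromosome 1, 612 in resilient against control and 561 in resilient against susceptible. Without chromosome 1 the numbers were 579, 545 and 511. Sizes ran from 55 to 85 bp, with a median of 70 bp, and positive shifts made up 51.6% (49.9 to 53.3), 51.0% (47.0 to 54.7) and 52.4% (48.1 to 56.5), intervals that include 50%. The largest shift in the authors' deposited table of susceptible against control was 85 bp at 67550562 of chromosome 15, between genes. Next in rank were shifts of 80 bp, which 817 positions of that table reached or passed, so that ties decided the order. In the authors' deposited tables, the first of these within named genes were -80 bp in 4930444P10Rik for susceptible against control, 80 bp in Daw1 for resilient against control, and 80 bp in A530032D15Rik and in C130026I21Rik for resilient against susceptible, all on chromosome 1. Near susceptible ACF1 segments, the authors' deposited table of resilient against control listed 80 bp at the promoter of A530032D15Rik and -80 bp in C130026I21Rik.

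A small share of H3 positions lay near ACF1 segments, but more than rotation gave. For the susceptible list this share was 0.909%, 1.82% and 1.92% of occupancy positions and 9.34%, 19.3% and 19.96% of shifts in susceptible against control, resilient against control and resilient against susceptible. Without chromosome 1 the shares were alike, at 1.64%, 1.64% and 1.76% of occupancy positions and 17.1%, 17.6% and 16.8% of shifts. Within 1000 bp of a susceptible segment lay 449 occupancy positions of susceptible against control, 2.95 times the mean of rotations, 319 of resilient against control (8.30 times) and 312 of resilient against susceptible (8.68 times). Shifts were more concentrated, with 368 (27.0 times), 118 (70.2 times) and 112 (70.0 times). Ratios for the control and resilient lists were of like size, and each of the 18 pairs reached the smallest two-sided permutation p, 0.0002 before and after adjustment. Without chromosome 1, the occupancy ratios lay between 7.80 and 11.3 and the shift ratios between 62.6 and 89.3. Moved by 50 kb to 1 Mb instead, outside chromosome 1, the segments still gave ratios from 5.34 to 23.6. Segments present in all 3 lists gave ratios from 7.95 to 26.9, and those of a single list from 0 to 10.3, with 11 of the 18 pairs past the threshold. The ratios of 0 came from 2 pairs with 0.393 and 0.557 positions in local moves. For susceptible-only segments the ratios were 2.03, 3.19 and 3.12 for occupancy and 4.16, 5.42 and 4.98 for shifts, and all 6 pairs passed (highest adjusted permutation p = 0.0139).

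**Figure D3:**
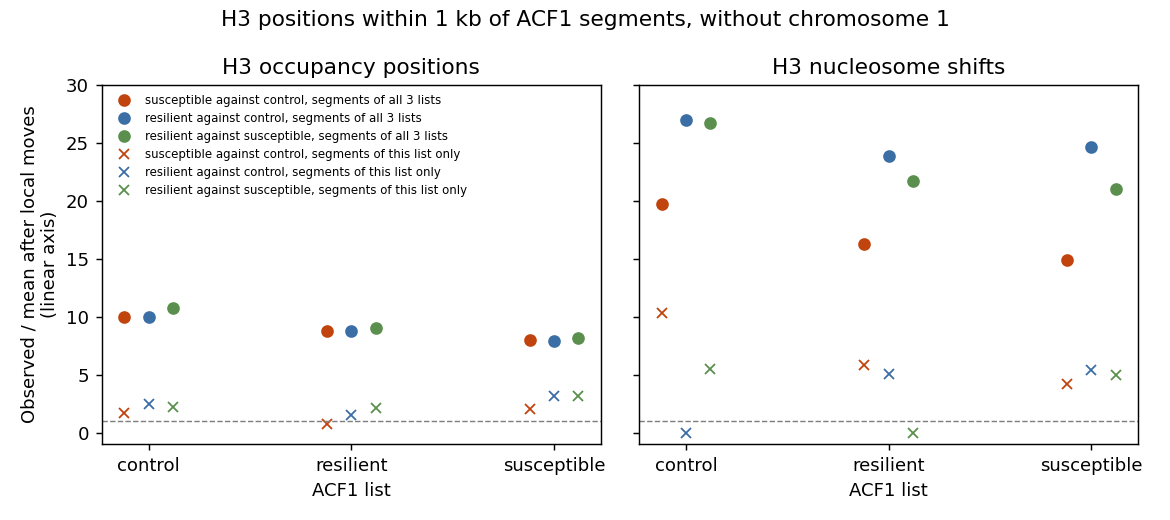
Observed number of H3 occupancy positions (left) and nucleosome shifts (right) within 1 kb of ACF1 segments, divided by the mean after moving each segment by 50 kb to 1 Mb (linear y axis, dashed line at 1), without chromosome 1. Circles stand for segments found in all 3 lists (7.95 to 26.9) and crosses for segments of 1 list only (0 to 10.3). Colours stand for the 3 comparisons.

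The direction of listed H3 positions near ACF1 segments differed from that elsewhere. Outside chromosome 1, 56.6% (47.1 to 63.8) of positions near susceptible segments were Up in susceptible against control, against 40.1% elsewhere. In resilient against control 24.6% (15.9 to 35.1) were Up, against 38.6%, and in resilient against susceptible 25.8%, against 49.2%. Each of these reached a permutation p of 0.0002, two-sided (adjusted p = 0.000257). The shuffle lays signs of several blocks over a dense locus and so breaks runs of 1 direction there. The permutation p-values of direction may therefore be too small. Near control segments the shares were 59.0%, 22.6% and 23.1%, and near resilient segments 64.0%, 27.9% and 29.5%, but the lists are not independent here. The interval of the 27.9%, for resilient against control, was 16.9 to 40.0 and included the 38.5% elsewhere. Of the positions near segments of each list in susceptible against control, 193 of 217 (control), 179 of 200 (resilient) and 196 of 272 (susceptible) lay near segments of all 3 lists. With chromosome 1 included, the susceptible against control share near susceptible segments was 39.2%, against 14.6% elsewhere (permutation p = 0.0002). Near segments of 1 list only, 0 of the 9 differences passed after adjustment; the lowest permutation p was 0.0156 (adjusted p = 0.14), for susceptible segments in resilient against susceptible.

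**Figure D4:**
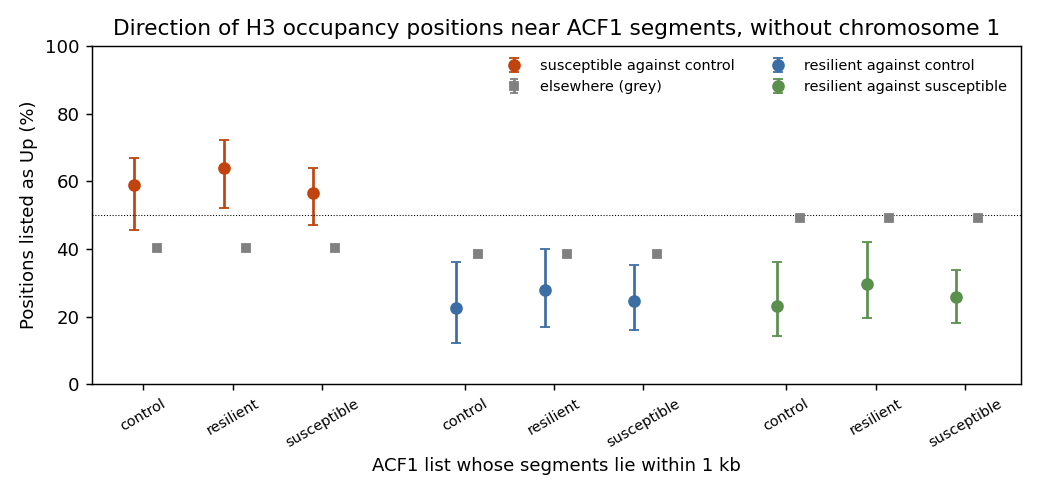
Percentage of H3 occupancy positions listed as Up within 1 kb of the segments of each ACF1 list (circles) and elsewhere (grey squares), without chromosome 1. Bars are 95% intervals from resampling 1 Mb blocks. Susceptible against control lies above its grey squares (56.6% to 64.0% against about 40.1%), and the 2 comparisons of resilient mice lie below theirs.

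Few occupancy positions lay near a shift, though more than rotation gave: without chromosome 1 they were 0.415%, 0.310% and 0.461% of the 3 tables. Outside chromosome 1, 69 occupancy positions of susceptible against control lay within 1000 bp of a shift, 8.42 times the mean of rotations, 50 of resilient against control (6.73 times) and 69 of resilient against susceptible (10.6 times), each with a two-sided permutation p of 0.0002. With chromosome 1, the ratio in susceptible against control was 1.39 (1473 positions, permutation p = 0.0004).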

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

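Of the tests in this part, only the one that left out the fullest blocks was fixed before its result was seen; all others were chosen after it.

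The odds that an occupancy position lay on chromosome 1 were 22.6 times as high in susceptible against control as in resilient against control, and for shifts 47.2 times as high. Swapping the tables within 1 Mb blocks gave a permutation p of 0.0002 for both, the smallest possible, which restates the excess seen first. A loss of H3 along chromosome 1 in susceptible mice would return as Up positions in resilient against susceptible, but these were 1.03 times (0.946 to 1.11) as frequent per Mb there as on the other autosomes. A lower depth of the susceptible library would remove Up positions from susceptible against control, and these were 1.01 times (0.929 to 1.102) as frequent. Before 19.7 Mb the rate of Down positions was 1.24 times (0.999 to 1.52) that of the other autosomes, but that coordinate was picked from the same counts, so this is no test of a processing step that changed along the chromosome, which may be the cause and stays open.

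The share of Up positions near susceptible ACF1 segments, less the share elsewhere, was 30.4 percentage points higher in susceptible against control than in resilient against control (permutation p = 0.0002, without chromosome 1); the opposite signs were seen first and both tables use the control library, so this p restates them and does not compare animals. Without the 5 blocks of 1 Mb that held the most positions, the difference from elsewhere fell from -13.95 to -9.65 points in resilient against control (permutation p = 0.0154), the comparison where it was least certain. It fell from 16.5 to 11.8 in susceptible against control and from -23.5 to -18.6 in resilient against susceptible. In resilient against control, Sfi1, Mid1 and Gm13152 were left out, so they did not make up the whole difference there. The shuffle breaks runs of 1 direction within a locus, and dense loci such as Rn45s stayed in. This p-value thus cannot decide whether a few loci are the cause. Whether susceptible-only segments stand for ACF1 gained in susceptible mice is unknown, as are the bound state and the depth. If they did and direction followed this gain, the share would be at least as high near them as near segments of all 3 lists. It was -15.8 points from it, 43.9% of 41 positions against 59.7% of 196, with a permutation p of 0.123, and so ACF1 gained in susceptible mice cannot be told apart from other causes. Copy number differences between the pooled animals stay open too, as the input libraries were not analysed here.

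The mitochondrial chromosome, which held no H3 position in any table and 2 or 3 ACF1 segments per list, was in the minority state over 86.4% of its length in the resilient list, against 16.0% in controls and 29.6% in susceptible mice.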

How the results depend on the processing

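Over all alternatives, 254 values kept their direction and side of the threshold or stayed within the stated range, 12 moved, 9 grew weaker and 7 turned round; leaving out chromosome 1, the 100 bp tolerance and the split by list were chosen after seeing the data. The wider part of each ACF1 list held 374 control, 358 resilient and 566 susceptible segments, and the larger shifts numbered 1971, 306 and 280, smaller by construction. Without chromosome 1, susceptible against control held 16617 occupancy positions with 40.4% Up and 579 shifts with 53.9% positive, and its exact positions had the same sign as in resilient against susceptible in 0.131%, against 10.0% with it, by the positions left out. Within 100 bp, 98.1% of positions agreed in sign between the 2 comparisons with control, against 99.7%. At 1 bp overlap, occupancy and shift coincided 11.2 times as often as in rotations in susceptible against control (6 positions, permutation p = 0.0926). With segments of 1 list only, without chromosome 1, ratios to local moves no longer past the threshold were 1.69 (control list) and 0.782 (resilient list) for occupancy in susceptible against control and 1.54 (resilient list) in resilient against control; for shifts they were 0 (control list) and 5.03 (resilient list) in resilient against control, and 5.51 and 0 in resilient against susceptible. The Up difference near such segments was -1.96, -23.8 and 3.49 points (control, resilient and susceptible lists) in susceptible against control, -10.6, 16.2 and -5.03 in resilient against control, and -2.14 and 17.9 (control and resilient lists) in resilient against susceptible; few positions lay there, and the cause was not tested. These counts go by p before adjustment; the difference that kept its side, -16.7 (susceptible list, resilient against susceptible), had an adjusted permutation p of 0.14. The stronger part of the occupancy tables could not be taken, since these rank no position; 50% overlap of 1 bp positions equals the main setting; the gene-list window was not run. Depth is unknown, so what it limits cannot be said.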

Other observations

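The tests in this part were chosen after the result was seen.

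H3 positions had their own distribution over gene classes. Outside chromosome 1, gene deserts had a higher share of Up positions than gene bodies in susceptible against control, 46.5% (44.6 to 48.2) against 37.6% (36.1 to 39.1), and in resilient against control, 46.2% (44.3 to 48.1) against 37.2% (35.6 to 38.8). In resilient against susceptible the shares were 50.3% and 50.3%. The 2 comparisons with a difference share the control library, so they are not independent. The X chromosome held 83, 74 and 101 occupancy positions in the 3 tables, about 0.498, 0.444 and 0.606 per Mb, against 6.68, 6.65 and 5.86 on chromosome 2, while it held 112 of the susceptible ACF1 segments.

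A pattern a reader may want to follow up is that H3 positions of every comparison gathered at ACF1 segments of every list. If both only lay in the same broad domains, moving segments by 50 kb to 1 Mb would keep the numbers, but the lowest of the 18 ratios was 3.19. If remodelling followed ACF1 gained in susceptible mice, positions near susceptible-only segments would be more frequent in susceptible against control than in resilient against control. The odds ratio was 0.631 (0.413 to 0.918, block bootstrap), with 41 against 63 positions, and resilient against susceptible held 59. That interval covers clustering along the genome and not differences between libraries. With 1 library per group, and depth and the bound state unknown, the odds ratio cannot decide this. Reads shared between gene copies could give both signals at once: genes with a segment had a neighbour of the same symbol root with an odds ratio of 1.07 (0.753 to 1.502) to other genes, and of 1.94 to genes of like length. Only 72.1% of them had a usable root, so this check is void and reads shared between gene copies stay open.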
